A study of Mus musculus with 2 samples.

How the data were processed

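Trimethylation of lysine 36 on histone H3 (H3K36me3), a mark laid down behind elongating RNA polymerase II, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in midbrain of C57BL/6NCrl mouse embryos at embryonic day 15.5. Per the labels, replicate 1 was a pool of 78 embryos with 3 technical replicates and replicate 2 a pool of 62 embryos with 2 technical replicates, both of mixed sex, with fragments of 300 to 500 bp. The replicates were therefore separate pools of animals. Both belong to 1 group, and no second tissue, age or treatment enters any comparison.

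The files are 4 deposited peak lists on the mouse build mm10. Per the file headers, 1 list was called on each replicate with its technical replicates together, 1 list on the reads of both replicates pooled, and the list of replicated peaks was derived from the other 3. The peak caller, its version, the aligner and the rule by which a peak counted as replicated are not given in the sources used here. In each list the authors deposited a display score of at most 1000, an enrichment signal per peak, and −log10 p and −log10 q values per peak. The enrichment signal, the score and the −log10 values are the authors' own and were used here to describe, rank or filter peaks within a list. The enrichment signal was also compared in rank between the replicates' lists. The lowest −log10 p value in the deposited lists lay between 2.01 and 2.03. Read totals are not given in the sources used here, so the sequencing depth of each replicate is unknown, and no detection limit was computed.

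Genes were taken from GENCODE release M21, which uses the same build, and chromosome lengths and soft-masked repeats from the matching RefSeq assembly. No peak or gene end lay beyond a chromosome end. Of each gene symbol the longest protein-coding gene was kept, which left 21911 protein-coding genes on chromosomes 1 to 19, X and Y. Peaks on unplaced scaffolds were left out of every comparison.

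For each gene and replicate the percentage of the gene body inside peaks was computed, and a gene with at least 10% in both replicates is called marked. Values are given as the mean of the 2 replicates ± SD. For a gene list the value is the median over members of these means, and its SD is that of the 2 replicates' own medians, so the value can lie outside the replicate medians. Overlap of the replicates was the share of one list's peaks with at least 50% of their length inside the other list. That overlap and the share of peak bases in gene bodies were set against 100 random circular shifts of the peaks along each chromosome, whose smallest possible p is 0.0099 (one-sided). Profiles used 10 equal parts (deciles) of the bodies of genes of at least 5 kb. Exons were compared with introns in marked genes without the first exon. Flanks were the 5 kb before and after each coding gene without bases inside any annotated gene. Domains were replicated peaks merged across gaps of up to 1 kb (1000 bp).

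A total of 26 gene lists were written before the data were examined, together with the tests, the other settings and the rule for named genes. They hold general machinery (ribosomal proteins, splicing and RNA polymerase II, the H3K36 methylation machinery, cell division), cell types and regions of the brain (neural progenitors, neurons, synapse, axon guidance, midbrain patterning and dopamine neurons, midbrain GABA and glutamate neurons, forebrain factors, oligodendrocyte lineage, astrocytes, microglia, endothelium and pericytes, red blood cells), other tissues (liver, muscle), Hox genes, imprinted genes, chromatin regulators linked to neurodevelopmental disorders, and 5 families by symbol (olfactory receptors, vomeronasal receptors, zinc finger genes named Zfp, clustered protocadherins, keratins). Ahsp of the red blood cell list was not matched, and the H3K36 machinery list kept 23 of 25 symbols. Each list's median percentage was compared with 10000 random lists of the same size, drawn with replacement from the other coding genes and matched on gene length in 20 bins; the range given for random lists is their central 95%. The two-sided p is a permutation p, its smallest possible value is 0.0002, and p-values were adjusted over the 26 lists by the Benjamini-Hochberg method. This p resamples genes, which are not replicates, so it does not measure variation between pools of embryos. The list test was checked on simulated coverage of 21911 genes: 1 of 100 lists of 30 genes was called with nothing added, 94 with 2 percentage points added and all 100 with 5. There, lists were called on an unadjusted p, fewer genes were at 0 than in the real data, and the points were added to every member. In the real data the central 95% of random lists ended at 7.38% for the 32 cell division genes. These counts therefore do not give the power of the test on the real lists.

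Named genes were the 15 coding genes of at least 5 kb with the highest coverage among marked genes, the 2 highest and the lowest member of each list (ties by symbol), the genes of the 5 widest domains, the 5 genes of at least 5 kb with the largest difference between replicates in each direction, and En1, En2, Otx2, Lmx1b, Foxa2, Th, Foxg1 and Setd2. Other genes named in the text were chosen after their values were seen. The other settings were a threshold of −log10 q of at least 5, the same number of strongest peaks per replicate, the replicated and the pooled list in place of the replicates, each replicate left out, and settings of single results (overlap rule, gene set, gene length, flank width, exons used, share of the body, list statistic, matching, gap of domains). Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.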

Results

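H3K36me3 was profiled by ChIP-seq in midbrain of mouse embryos at embryonic day 15.5, in 2 replicates that were separate pools of 78 and 62 embryos. Replicate 1 had 122923 deposited peaks over 41.4 Mb and replicate 2 had 140792 over 55.7 Mb, with median widths of 263 and 288 bp. The list called on the pooled reads held 166841 peaks and the list of replicated peaks 87354, with a median width of 515 bp. Of the replicated peaks 74.3% overlapped both replicates' lists by at least 1 base, 47.5% had 50% or more of their length in both, and 1.48% overlapped neither, so the name of that list does not mean a peak in each replicate. The median enrichment given by the authors was 2.82 in replicate 1 and 3.07 in replicate 2, and 76.9% and 90.9% of their peaks had a q below 0.05. The read depth behind these lists is unknown. The design holds 1 tissue at 1 age, so the comparisons below are between replicates, between parts of the genome and between groups of genes.

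The first comparison asked how far the replicates shared their peaks. Of the replicate 1 peaks, 56.6% had at least 50% of their length inside replicate 2 peaks, against a mean of 2.37% after random shifts (23.9-fold, permutation p = 0.0099, the smallest that 100 shifts can give). Of the replicate 2 peaks, 39.5% lay inside replicate 1 peaks, against 1.66% (23.8-fold, permutation p = 0.0099). Shifts also move peaks out of genes, where nearly all peak bases lay. The folds therefore cannot separate agreement of single peaks from a shared location in the same genes. Sharing rose with strength, from 37.8% in the weakest decile of replicate 1 peaks to 85.0% in the strongest, and from 24.4% to 69.8% in replicate 2. When 50% of both peaks had to overlap, 31.0% of replicate 1 peaks and 27.1% of replicate 2 peaks were shared. Peaks that overlapped a single peak of the other replicate agreed weakly in strength. Across 73593 replicate 1 peaks that overlapped exactly 1 replicate 2 peak by at least 1 base, the Spearman rho of enrichment was 0.215. Peaks that overlapped several replicate 2 peaks were left out of this value. Coverage of whole genes differed little in rank, with a Spearman rho of 0.931 between replicates across 21911 coding genes, which are not independent replicates. The rho was 0.914 across the 11018 genes with a peak base in at least 1 replicate. With peaks of −log10 q of at least 5 only, 53.1% of replicate 1 peaks lay in replicate 2 peaks, 78.5-fold over shifted peaks. In the other direction it was 10.1%, 70.5-fold over shifted peaks, since replicate 1 then kept 5457 peaks and replicate 2 kept 21963.

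H3K36me3 peaks lay almost entirely in the bodies of protein-coding genes. Coding gene bodies held 94.4% of peak bases in replicate 1 and 95.05% in replicate 2 and made up 38.2% of the chromosomes, an enrichment of 2.48 ± 0.01-fold (SD, n = 2). Shifted peaks gave a mean of 1.07-fold and at most 1.14-fold (permutation p = 0.0099 in each replicate). Exons of coding genes, 3.52% of the chromosomes, held 27.0% of peak bases in each replicate, and introns held 67.4% and 68.1%. The part of the genome outside all annotated genes and their flanks, 50.4% of the chromosomes, held 0.926% and 0.369% of peak bases.

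Within genes the mark lay toward the 3′ end. In 17779 coding genes of at least 5 kb, 1.05% ± 0.19 of the first decile of the body was in peaks and 7.91% ± 1.73 of the last decile, a ratio of 7.54 ± 0.30 (SD, n = 2). In the 4366 marked genes of that length, coverage went from 4.01% ± 0.95 in the first decile to 38.0% ± 7.8 in the ninth and 35.7% ± 7.5 in the last. Peaks also ran past the gene end. The 5 kb after coding genes was covered to 2.60% ± 0.57 and the 5 kb before them to 0.342% ± 0.079, a ratio of 7.61 ± 0.10. The ratio was 20.6 ± 1.2 for flanks of 2 kb. It was 66.3 ± 15.7 without bases that were downstream of one gene and upstream of another, a setting chosen after the data were seen. Both replicates showed each of these differences, and each was larger than their spread.

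**Figure D1:**
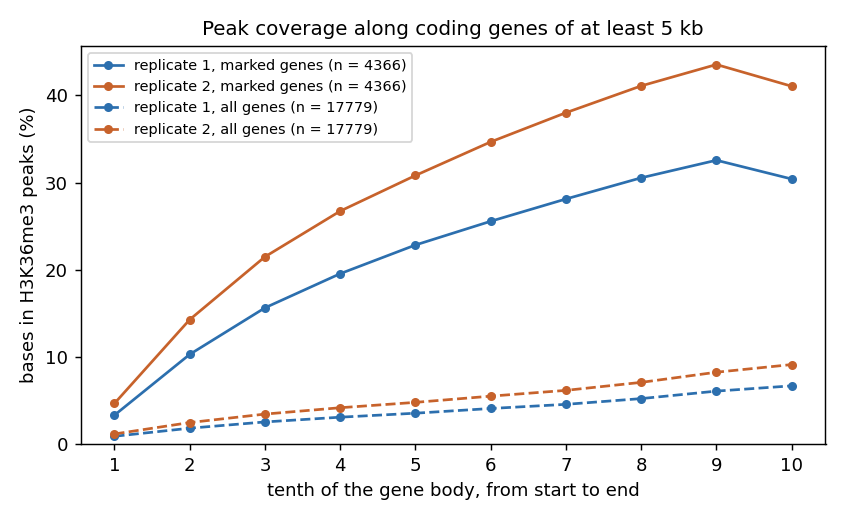
Percentage of bases in H3K36me3 peaks (vertical axis) in each decile of the gene body from start to end (horizontal axis), for each replicate, in all coding genes of at least 5 kb (dashed) and in marked ones (solid). Coverage of marked genes rose from a mean of 4.01% in the first decile to 38.0% in the ninth as the mean of both replicates, with replicate 2 above replicate 1 throughout.

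Exons of marked genes carried more of the mark than their introns. In marked genes 40.7% ± 7.9 of exonic bases beyond the first exon and 22.8% ± 5.0 of intronic bases were in peaks. With bases pooled over genes, the ratio was 1.82 in replicate 1 and 1.76 in replicate 2, a mean of 1.79 ± 0.05. Within single genes, exons were covered more than introns in both replicates in 3499 of 4642 marked genes (75.4%) and less in both in 469 (10.1%). Dync1h1, the heavy chain of cytoplasmic dynein, had 87.6% of its exonic bases and 67.9% ± 8.5 of its whole body in peaks. Setd2, the enzyme that trimethylates H3K36, had 61.4% of its exonic bases and 20.1% ± 6.1 of its 86.0 kb body in peaks (chromosome 9, 110532597 to 110618633). In Zfp68 and Atxn2l the exonic bases, at 60.7% and 63.3%, were covered less than the whole body, at 68.0% and 68.1%.

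A total of 4691 of 21911 coding genes (21.4%) were marked, and 10893 (49.7%) had no peak base in either replicate. Another 145 genes reached 10% of the body in replicate 1 only and 1077 in replicate 2 only. Marked genes made up 7.87% of genes under 5 kb, 26.2% of those from 5 to 20 kb, 28.8% of those from 20 to 100 kb and 6.27% of longer ones. The Spearman rho of gene length and percentage covered was 0.264 ± 0.024 (n = 2 replicates, across genes). The count of marked genes depended on the threshold: 362 genes were marked with peaks of −log10 q of at least 5, 2529 at 20% of the body, 6301 at 5% of the body and 6926 with the pooled list.

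Among coding genes of at least 5 kb, 6 of the 15 with the highest coverage were Zfp zinc finger genes. Zfp606 (ENSMUSG00000030386.18, chromosome 7, 12478293 to 12496235, plus strand) had 82.8% ± 1.8 of its body in peaks and Zfp110 on the same chromosome (ENSMUSG00000058638.14, chromosome 7, 12834761 to 12850577) 77.5% ± 4.6. Zfp90 had 74.1% ± 0.8, Zfp2 73.6% ± 1.9, Zfp68 68.0% ± 5.8 and Zfp354c 68.0% ± 4.1. Fasn, the fatty acid synthase (chromosome 11, 120805846 to 120824547), had 71.9% ± 6.6. The translation factor gene Eif4g2 had 69.7% ± 8.3, Sptan1, which encodes a spectrin of the membrane skeleton, 68.9% ± 11.2, and Prpf8, a core protein of the spliceosome, 68.7% ± 8.1. Prrc2a, Leng8, Ccdc177, Atxn2l and Dync1h1 completed the 15 highest of that length, between 67.9% and 68.8%.

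Of the 26 gene lists, 7 passed the test with a median above length-matched random lists, each with an adjusted permutation p of 0.00074, and none passed with a median below. Splicing and RNA polymerase II genes were covered to a median of 36.6% ± 9.1, with 28 of 32 members marked. Among them Prpf8 and Sf3b3 (67.5% ± 8.0) were highest, and Ptbp2, a splicing regulator of neurons, lowest at 6.27% ± 0.88. Ribosomal protein genes had a median of 21.7% ± 6.6 with 27 of 42 marked, from Rps5 at 59.2% ± 19.8 and Rps3 at 54.2% ± 22.5 to the X-linked Rpl10 with no peak base. Genes that write, read or erase H3K36 methylation had a median of 20.4% ± 6.1 with 16 of 23 marked. The demethylase gene Kdm4a had 56.9% ± 15.9 and the elongation factor gene Supt6 51.6% ± 7.6, while Phf19 had no peak base. Chromatin regulators linked to neurodevelopmental disorders had a median of 19.2% ± 5.2 with 22 of 38 marked, led by the chromatin remodelling subunit gene Smarcc2 (63.4% ± 11.8) and the H3K4 methyltransferase gene Kmt2d (63.0% ± 10.6). Foxp2 was the lowest of that list at 0.042% ± 0.059. These 7 calls held under every alternative tried, but that of the clustered protocadherins rests on overlapping genes.

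Pan-neuronal genes were covered above genes of the same length. They had a median of 7.69% ± 2.20, above the central 95% of random lists, which ended at 2.61%, and 11 of 32 were marked. Random lists were drawn from all other coding genes, including those without a peak base, so this does not show a preference for neurons. The kinesin gene Kif1a reached 43.9% ± 11.7, Crmp1, a gene of axon growth, 35.6% ± 7.5, Stmn1 26.3% ± 4.9 and the neuronal tubulin gene Tubb3 24.4% ± 6.7, whereas Thy1 had no peak base. Synaptic genes had a median of 2.04% ± 0.08 and did not pass (adjusted permutation p = 0.179), with 6 of 34 marked, among them Stxbp1 (24.9% ± 7.3) and Nlgn2 (24.6% ± 13.1), and no peak base in Grin2a. Axon guidance genes did not pass either (adjusted permutation p = 0.796), with 5 of 36 marked, all but Sema3f plexin genes. Plxnb1 had 45.9% ± 6.6 and Plxnb2 39.4% ± 11.2, and Robo3 had no peak base.

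No gene of the lists of regional identity was marked over its whole body. No gene of the midbrain patterning and dopamine list was marked and 25 of 28 had no peak base in either replicate. En1, En2, Otx2, Lmx1b and Foxa2, transcription factors of the midbrain, and Th, the rate-limiting enzyme of dopamine synthesis, were among those 25. Pbx1 was the highest at 2.11% ± 0.40, followed by Pbx3 at 0.270% ± 0.035. Of the genes of midbrain GABA and glutamate neurons none of 32 was marked. Slc17a6, the vesicular glutamate transporter, had 5.13% ± 0.18 and Gad2, which makes GABA, 2.99% ± 0.40, and Barhl1 had no peak base. None of 25 forebrain factors was marked. Cux2 had 2.10% ± 0.45 and Bcl11b 2.09% ± 0.30, and Foxg1 and Arx had no peak base. All 39 Hox genes lacked a peak base. Long genes of these lists held more of the mark over exonic bases, which were covered to 44.7% in Zfhx3, 24.0% in Bcl11b, 15.5% in Pbx1, 15.2% in Cux2 and 12.8% in Slc17a6, while the median over exonic bases was 0 in each of the 4 lists. The median test cannot fall below a random median at or near 0. The adjusted permutation p of these 4 lists was 0.895 or 1. Compared by the share of members marked, an analysis also fixed beforehand, the same 4 lists lay below random lists (adjusted permutation p from 0.0052 to 0.0142). Peaks were called on chromatin of all midbrain cells together. A gene without a peak may therefore still carry the mark in a minority of the cells.

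Neither the list of neural progenitors nor that of cell division passed, by the median or by the share of members marked. For the share the adjusted permutation p was 0.523 for neural progenitors and 0.481 for cell division. Of all coding genes 21.4% were marked. Neural progenitor genes had 2 of 26 marked, Dll1, a Notch ligand gene, at 24.7% ± 6.5, and Msi1 at 21.6% ± 8.1, and Ascl1 had no peak base (adjusted permutation p = 1). Cell division genes had 6 of 32 marked (adjusted permutation p = 0.895), and 8 of 32 had no peak base. The highest were Cdk4 at 50.1% ± 3.4, with 14.6% of its body shared with Tspan31, and the replication gene Mcm7 at 33.6% ± 8.0. Aurkb had no peak base.

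Few markers of other cell types were marked. Here too the peaks came from all cells together, so they cannot show the state of genes used by a minority of cells. In the astrocyte list 2 of 17 genes were marked, Glul (32.1% ± 11.6) and Atp1b2 (14.8% ± 0.6), and Agt had no peak base. In the microglia list 2 of 21 were marked, Cd68 (67.8% ± 30.4, 1.94 kb long) and Fcer1g (12.4% ± 0.8), and Aif1 had no peak base. In the oligodendrocyte list Cnp alone of 18 was marked, at 38.5% ± 4.1, and 53.0% of its body is shared with Dnajc7. Mog had 7.30% ± 3.05 and Cldn11 no peak base. No gene of the endothelium and pericyte (23), red blood cell (17), liver (25) or muscle (30) lists was marked. Their highest members were Slc2a1 at 4.22% ± 1.22, Alas2 at 2.05% ± 1.11 with its whole body shared with Apex2, Hnf1a at 1.40% ± 0.79 and Ttn at 1.63% ± 0.55. These lists had adjusted permutation p of 0.895 or more in the median test, and endothelium, liver and muscle lay below random lists in the share of members marked (adjusted permutation p of 0.0221, 0.00817 and 0.00208). The astrocyte, microglia, oligodendrocyte and red blood cell lists passed neither test, with adjusted permutation p of 0.705, 0.470, 0.123 and 0.0583 for the share.

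**Figure D2:**
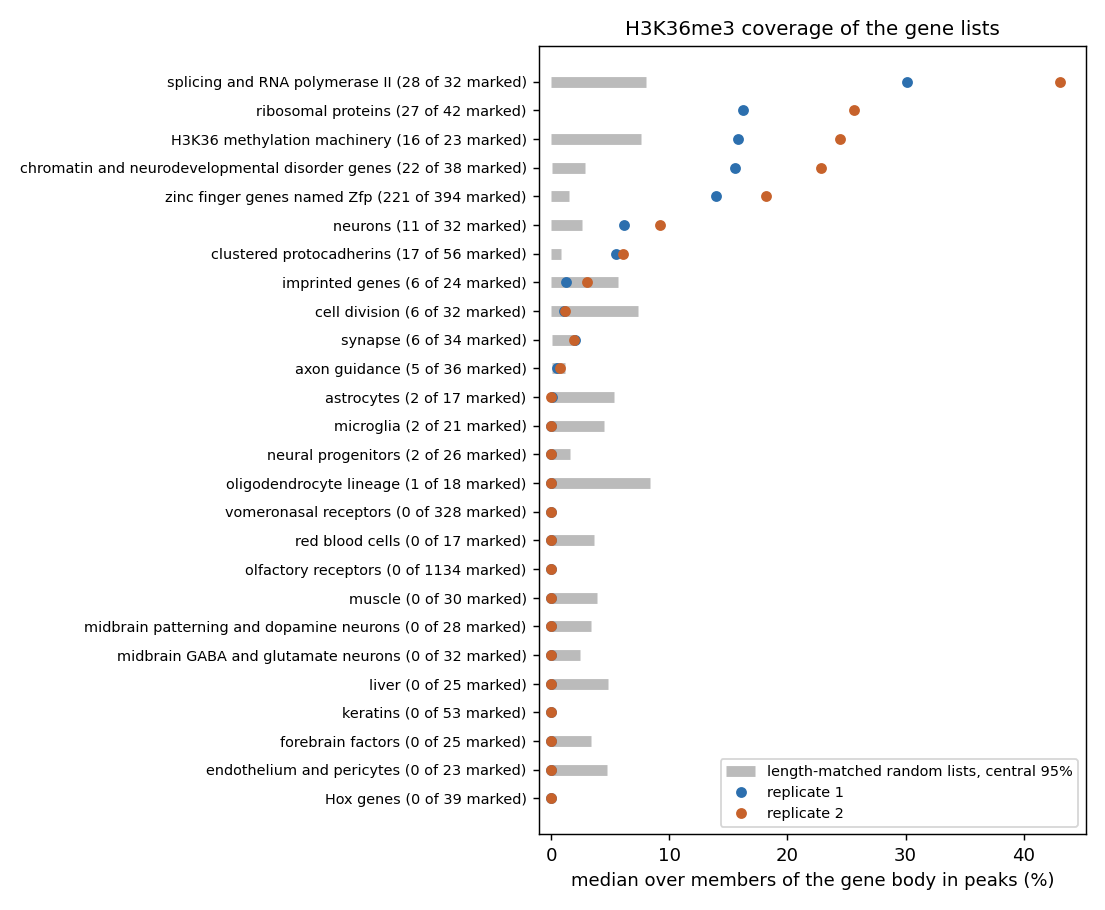
Median over list members of the percentage of the gene body in peaks (horizontal axis) for each of the 26 gene lists (vertical axis) in both replicates, with the central 95% of length-matched random lists as grey bars. Both replicates of 7 lists lie to the right of the bars, from clustered protocadherins (median 5.63%) to splicing and RNA polymerase II (36.6%).

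Gene families behaved differently from one another. Zfp genes had a median of 15.9% ± 3.0 with 221 of 394 marked, against a random median of 0.492%, and Zfp114 had no peak base. Clustered protocadherins had a median of 5.63% ± 0.41 with 17 of 56 marked. The bodies of these genes overlap, so that Pcdhga3 (26.1% ± 5.2) and Pcdhga2 (25.8% ± 5.2) share most of their peaks and are not separate measurements. All 17 marked members are nested gamma cluster genes, and the random lists are of separate genes, so the p of this list is too small. None of 1134 olfactory receptor genes, 328 vomeronasal receptor genes or 53 keratin genes was marked, and 1131, 322 and 52 of them had no peak base. These 3 families also lay below random lists in the share of members marked (adjusted permutation p = 0.00065). Imprinted genes did not pass (adjusted permutation p = 0.687), with 6 of 24 marked. Nnat had 47.1% ± 9.5 and lies inside Blcap, Igf2r had 24.2% ± 4.7, and Cdkn1c had no peak base.

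Coding genes on chromosome X were covered far less than those on any autosome. Peaks held 0.567% ± 0.111 of coding gene bases on chromosome X, and from 3.09% to 6.68% on the autosomes. The ratio of chromosome X to the median autosome was 0.125 in replicate 1 and 0.121 in replicate 2, a mean of 0.123 ± 0.003. Of 948 X-linked genes 21 were marked (2.22%), against 14.3% to 29.5% on the autosomes. Within marked genes the ratio was 0.774 ± 0.036. Marked genes were chosen by their coverage, the quantity compared, with the same minimum on every chromosome. The ratio within them therefore cannot show how far active X-linked genes were covered relative to autosomal ones. With peaks of −log10 q of at least 5 the ratio was 0.0432 over all genes. None of 183 genes on chromosome Y was marked.

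**Figure D3:**
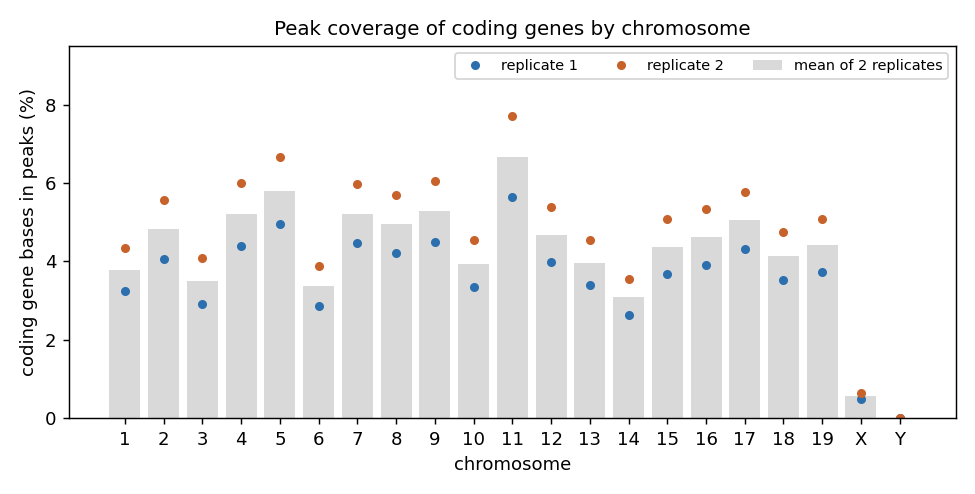
Percentage of coding gene bases in peaks (vertical axis) by chromosome (horizontal axis), as the mean of 2 replicates (bars) with each replicate as a point. Chromosome X at 0.567% lies below every autosome, of which the lowest has 3.09%.

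Replicated peaks merged into 33291 domains with a median width of 1.01 kb, of which 1394 were wider than 10 kb and 227 wider than 20 kb. The widest covered 84.0 kb inside Hectd4 (chromosome 5, 121284593 to 121368560), a ubiquitin ligase gene. The next were 77.0 kb inside Ubr4 (chromosome 4, 139400286 to 139477265), 72.6 kb inside Trrap (chromosome 5, 144782575 to 144855189), 57.6 kb over Dync1h1 (chromosome 12, 110612362 to 110669957) and 54.5 kb over Sptan1 (chromosome 2, 29978489 to 30032977). With no gap allowed there were 87333 domains, the widest 14.3 kb.

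Some genes of at least 5 kb differed widely between the replicates. Smim7 was 38.2 percentage points higher in replicate 2 (15.5% and 53.7%), Snrpa 35.2, Rps28, which shares 70.3% of its body with Kank3, 32.3, Ftsj3 32.2 and the proteasome gene Psmc4 31.8. Naa10 on chromosome X had 24.9% in replicate 1 and no peak base in replicate 2, with 98.5% of its body shared with Arhgap4. Rpl22 had 36.7% and 18.4%, Fahd2a 24.5% and 7.10%, Cuedc2 20.8% and 5.06%, and Spata2 17.8% and 3.43% in replicates 1 and 2. With 1 pool of embryos behind each value these differences were not tested. Replicate 2 peaks covered more bases in total, 55.7 against 41.4 Mb, and the differences were not corrected for this.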

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

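The ubiquitous X-linked gene list, the comparison with the pooled reads and the receptor share were chosen only after the results they bear on were seen, and the other tests in this part were fixed before their values were computed.

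Outside the coding genes, 10 of 4574 lincRNA genes at least 5 kb from any coding gene had at least 10% of the body in peaks in both replicates (0.219%). They include Meg3 at 16.6% ± 6.8, Mirg at 19.5% ± 12.4 and B830012L14Rik at 29.3% ± 0.7, which lie within the same stretch of chromosome 12, from 109541001 to 109749460, a region known for imprinted noncoding RNAs. Unplaced scaffolds, which entered no comparison, held 38 peaks of replicate 1 and 44 of replicate 2.

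Coding genes on chromosome X had 0.123 of the median autosome's coverage. Leaving out soft-masked bases gave 0.137 ± 0.003, which argues against soft-masked repeats as the cause. Mappability of the other bases was not tested. A lower number of active genes was weighed with 74 X-linked genes listed as ubiquitously expressed. Of these 12.2% were marked, while 60.0% to 90.3% of the autosomal members of the chromatin, ribosomal and splicing lists were. Those lists had already been found above random lists and were not matched to the 74 genes on length or expression. In the cell division list 18.75% of members were marked, and on the median autosome 22.2% of coding genes. No expression was measured here, so the comparison cannot show how many of the 74 genes were active. A peak base was present in 67 of the 74 (90.5%), and 2.22% of all X-linked genes were marked. Fewer active genes therefore stay open as a cause. The single active X copy per cell, against 2 copies of each autosome, may put X-linked peaks near the caller's threshold. The ratio was 0.163 in the list called on pooled reads, above both replicates, but any weaker signal on chromosome X would raise it too, so this cannot be told apart from a lower level of the mark.

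Zfp genes were covered more than genes of the same length. Reads shared between tandem Zfp genes as the whole cause are argued against by the 126 Zfp genes with no other Zfp gene within 500 kb. Their median was 12.6%, above the central 95% of random lists, which ended at 2.14% (permutation p = 0.0002, the smallest possible). The 268 genes with another Zfp gene within 500 kb had a higher median, 17.7%, so a part from tandem copies stays open. Zinc finger genes under other names were not counted as neighbours. The test fixed beforehand for multicopy family membership compared median coverage of the receptor families with random lists, and it decided nothing, since the medians were 0 on both sides. By the share of members marked, a measure chosen afterwards, 0 of 1462 receptor genes were marked against 21.8% of length-matched genes, and a family without any marked member has no signal for paralogs to share, so this decided nothing either. Multicopy membership, nearby paralogs under other names and paralogs farther away than 500 kb stay open, and no biological explanation was tested.

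Exons were covered 1.79 times as much as introns in marked genes, with bases pooled over genes. The ratio was 1.70 ± 0.04 without soft-masked bases, 1.98 ± 0.04 in 200 bp windows matched on GC content (2.08 and 2.01 in the replicates without matching) and 1.44 ± 0.04 within the same decile of the gene, and these argue against repeats, GC content and position along the gene as the whole cause. Part of the difference went with position, as the value within deciles lies below 1.79. All these ratios pool bases over genes and the checks were not combined, so they do not separate differences within genes from differences between genes. Within single marked genes exons were covered more in both replicates in 75.4% and less in both in 10.1%, without matching on position. No biological explanation was tested, and a difference between exons and introns in the mark itself may remain as a hypothesis.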

How the results depend on the processing

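Settings other than the flank overlap were planned before the data were examined. Replicate overlap stayed above shifted peaks in every setting, and the 7 gene lists above random lists stayed above in all 9 alternatives. With peaks of −log10 q of at least 5, the genic enrichment was 2.51, the last-to-first-decile ratio 10.3, the exon-to-intron ratio 2.40, the flank ratio 7.34, the length rho 0.206, the chromosome X ratio 0.0432 and the number of marked genes 362. With the replicated list these were 2.4996 (genic), 8.49 (deciles), 0.228 (length) and 0.102 (chromosome X), and with the pooled list 7.03 (deciles), 1.63 (exons), 7.74 (flanks) and 0.163 (chromosome X). Other moves were 2.13 for all annotated genes, 6.68 for genes of at least 20 kb, 1.65 with all exons, 20.6 for 2 kb flanks, 66.3 without bases in both flanks (added after the data were seen), 0.774 for marked X-linked genes, 2529 marked genes at 20% of the body, 10 lists below random lists by share of members marked, and 87333 or 18275 domains with no gap or a gap of 3 kb. The strict threshold keeps fewer peaks, and the domain counts follow from the gap. Marked genes were chosen by their coverage, so the 0.774 does not test the chromosome X result. The cause of the other moves was not tested. None of these values and none of the 7 lists above random lists changed direction. Leaving out each replicate gave 2.47 to 2.49 (genic), 7.33 to 7.76 (deciles), 1.76 to 1.82 (exons), 7.54 to 7.68 (flanks), 0.247 to 0.281 (length), 0.121 to 0.125 (chromosome X) and 4836 to 5768 marked genes. Of 161 values of the 15 highest and the 8 preset genes 50 moved by more than the replicate spread. No paired analysis was possible because there is 1 group. Unknown read depth limits what a gene without peaks can show.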

Other observations

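The gene families in this part were chosen after the data were seen, and p-values were adjusted over 15 families.

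Several protein complexes used by most cells were covered well above genes of the same length. Chaperonin subunit genes, which encode the complex that folds actin and tubulin, had a median of 48.1% ± 8.5 with 7 of 8 marked, led by Cct3 at 63.8% ± 9.3. Nuclear pore genes had 30.9% ± 7.8 with 16 of 20 marked, and proteasome subunit genes 30.1% ± 9.1 with 29 of 39 marked, led by Psmc1 at 57.2% ± 7.0. Translation initiation factors had 27.0% ± 7.3 with 37 of 55 marked, Mediator subunits 16.6% ± 2.0 with 19 of 30, mitochondrial ribosomal proteins 15.1% ± 3.8 with 42 of 78, and ubiquitin-specific proteases 14.4% ± 3.4 with 27 of 50. Each of these 7 families had an adjusted permutation p of 0.00037. Zscan and Zkscan genes, zinc finger genes under other names than Zfp, had 21.8% ± 4.1 with 18 of 27 marked (adjusted permutation p = 0.00037). Dynein subunit genes had 24.5% ± 7.0 with 4 of 7 marked (adjusted permutation p = 0.0063), but did not pass in the share of members marked (adjusted permutation p = 0.0676).

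Kinesins did not pass (median 1.495% ± 0.30, adjusted permutation p = 0.866), although Kif1a had 43.9% ± 11.7 and Kif21b 39.4% ± 6.1. In the share of members marked, 4 families lay below random lists, with 0 of 93 cytochrome P450 genes, 1 of 82 interleukin and interleukin receptor genes (Il18bp, 42.0% ± 6.6), 3 of 69 Gpr genes and 62 of 361 solute carriers. The adjusted permutation p was 0.0003 for each but Gpr genes, where it was 0.00055. Keratin-associated proteins did not pass that test, with 0 of 57 marked against 1.75% of random genes (adjusted permutation p = 0.388).

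Most of the strongest peaks were in zinc finger genes. Of the 50 replicated peaks with the highest enrichment 38 overlapped a Zfp gene, against 2080 of all 87333 (2.38%). The first was in Zfp386 (chromosome 12, 116058318 to 116061148) and the next in Zfp68 and Zfp37. Several of the 38 lay in the same gene, as in Zfp68 and Zfp2, so they are not separate measurements. Reads shared between paralogs were not tested for these peaks. The 21 marked genes of chromosome X were led by Kdm5c (26.6% ± 7.4), Maged1 (26.5% ± 3.7), Flna (26.2% ± 6.5) and Uba1 (25.04% ± 9.02).

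The rise of coverage toward the gene end had 3 tests fixed before their values were computed. The ratio of the last to the first decile was 10.4 ± 0.5 in 4174 genes with no other annotated gene within 5 kb, 7.89 ± 0.31 without soft-masked bases and 6.23 ± 0.29 over intronic bases, against 7.54 over all bases.

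A total of 141 domains (0.424%) had no annotated gene within 5 kb. The widest spanned 6.12 kb on chromosome 5, from 104582130 to 104588250, with 57.9% of its bases in replicate 1 peaks and 68.7% in replicate 2 peaks.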
